A study of Mus musculus with 4 samples.

How the data were processed

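RNA sequencing of liver Tregs from young Altre-WT and Altre-KO mice was analysed, with 2 libraries per genotype and 4 in all. Per the labels' protocols, RNA was extracted with a micro-scale column kit and libraries were made with a SMARTER kit for mRNA. Per the submitters' processing notes, STAR, cutadapt and DESeq2 were used with genome build mm10 (GRCm38); their roles, versions, the counter and the gene annotation are not given in the sources used here. The deposited table lists 24452 genes by symbols in capitals, with 1 column per library in 2 units.

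The first deposited unit is RPM, reads scaled to a common total, here a total larger than the reads on listed genes, plus an added 0.0001, as read from the values, since the column names give no unit. The second is CPM, per the file headers, which the authors scaled so that the listed genes of every library sum to the same total. The authors' deposited table also holds each genotype's mean signal in CPM, the log2 of their ratio (knockout over wild type), and a p-value and adjusted p-value from a test that the file headers do not name. Values of the authors' comparison are given as theirs and entered no test except a named alternative.

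What 1 read is worth in a library was estimated from the RPM values as their smallest common step. Between 92.9% and 93.8% of the values above 0 came out whole within a tolerance of 0.02 of a read and the rest were fractional, so the values were not treated as counts, and reads are called estimated. These steps imply 9710060 to 11570100 reads per library, of which 1828770 to 3266130 lay on listed genes. The share on listed genes was 18.8% (95% Wilson interval 18.8 to 18.9), 20.6% (20.5 to 20.6), 32.8% (32.76 to 32.81) and 21.5% (21.5 to 21.6) in wild-type replicates 1 and 2 and knockout replicates 1 and 2, and these intervals cover counting error only. Genes above 0 numbered between 14970 and 16668 per library. The 2 libraries of a genotype differed by more than sampling noise (chi-square over degrees of freedom 3.44 in wild type and 10.3 in knockout), so none was counted as a copy of another's reads. This does not tell whether they came from separate samples.

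The test planned before the data were examined assumed counts. As the unit was CPM, limma (version 3.58.1, R 4.3.3) was used, with moderated variances following the mean-variance trend (robust off) on log2(CPM + 1). Genes were tested where at least 2 libraries reached 10 estimated reads at the median depth, that is 4.22 CPM, which left 10486. Group was the only term. P-values were adjusted over all tested genes by the Benjamini-Hochberg method with a threshold of 0.05. Log2 fold changes are knockout minus wild type on the log2(CPM + 1) scale and understate the change of low genes. On data simulated for this comparison over 10486 genes, 17.5% of genes changed 1.5-fold were called, 67.5% at 2-fold, 95.7% at 4-fold and 98.5% at 8-fold. In the same runs, which also held changed genes, 0.0517% of unchanged genes were called. Every simulated gene had the same dispersion of 0.0155, taken from well-covered genes, so these shares do not cover genes that vary more between libraries.

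Before the data were examined, 41 gene lists were fixed, of T cell states and functions, signalling, mitochondria and metabolism, stress, proliferation, chromatin, translation, trafficking and other cell types. The 33 with at least 5 tested members were tested with camera (2-sided, preset inter-gene correlation 0.01), adjusted over the lists. Alternatives were camera with an estimated correlation and fry. With an estimated correlation, camera takes its degrees of freedom from the 4 libraries and not from the number of genes. A list can then hardly reach an adjusted p of 0.05, so a failure to pass that alternative does not decide on a call. Protein genes of the mitochondrial genome were not analysed here. Other cell types are given as sums of CPM over all listed markers.

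Named genes followed a rule also fixed in advance. It takes the genes past the threshold whose knockout values both lie on the same side of both wild-type values, leaving out predicted genes, clone names and antigen receptor segments, up to 12 in each direction. Where none pass in a direction, it takes the 5 with the smallest p, as values. It adds a panel of 14 Treg genes and, in each list described, the 3 members with the smallest p. Mouse symbols were matched by name to GENCODE M21 (23519 symbols) and, where that failed, to RefSeq symbols (269) or synonyms (558), and 106 were left as listed. Positions are from GENCODE M21. Near-identical transcripts were searched with blastn 2.17.0, and figures were drawn with matplotlib 3.10.9.

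Alternatives covered limma-voom on estimated reads, median-of-ratios size factors, upper-quartile scaling, library totals without ribosomal protein genes, the low-value filter, the pseudocount, the threshold, the replicate number as a block, leaving out each library, and for lists the test, background and ranking.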

Results

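Regulatory T cells (Tregs), the CD4 T cells that restrain immune responses and carry the transcription factor Foxp3, were taken from the livers of young mice of 2 genotypes: Altre-WT and Altre-KO, in which Altre, a long non-coding RNA of Tregs, was knocked out. RNA-sequencing libraries, made with an mRNA kit per the labels, numbered 2 per genotype. Gene levels are given in CPM, read counts scaled to the same total over the listed genes of each library. RNAs other than mRNA were abundant in every library, with Rpph1 at 30257 to 38161 CPM, Rmrp at 15245 to 17738 CPM and Rn45s at 13699 to 37757 CPM. The comparison asks which transcripts depend on Altre in Tregs of the young liver. The targeted transcript was not analysed here, so genotype labels were taken as given. Estimated reads on listed genes were 1828770 and 2378950 in the wild-type libraries and 3266130 and 2361930 in the knockout libraries. A single read was worth between 0.306 and 0.547 CPM. Cd4 lay between 527 and 547 CPM in the 4 libraries, Cd8a at or below 0.42 CPM and Cd8b1 between 4.66 and 8.83 CPM, while Foxp3 was at 160.4 and 140.5 CPM in wild type and at 79.5 and 162 CPM in knockout. Libraries did not pair off by genotype. Across genes, which are not independent replicates, Pearson's r of log2 CPM was highest between wild-type replicate 2 and knockout replicate 2 (0.969), against 0.964 within wild type and 0.965 within knockout. The labels do not say whether the 2 libraries of a genotype came from separate mice, so the spread between them can be technical. The limma p-values, SEs and intervals rest only in part on each gene's own spread between these libraries. With 20.8 prior degrees of freedom, they draw largely on the variance trend over all tested genes.

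Knockout Tregs had less of both stress-inducible chaperone transcripts of the heat-shock family, Hspa1b and Hspa1a. Hspa1b was at 309.1 and 702 CPM in wild type and at 81.1 and 87.4 CPM in knockout, 5.48-fold lower (log2 fold change -2.45, SE 0.24, limma adjusted p = 4.26e-06). Hspa1a was at 117 and 325 CPM in wild type and at 17.8 and 29.8 CPM in knockout, 8.15-fold lower (log2 fold change -3.03, SE 0.32, limma adjusted p = 1.08e-05). The peptide transporter gene Slc15a2 fell from 75.6 ± 9.54 CPM to 12.1 ± 14.6 CPM (SD, n = 2 per genotype, log2 fold change -3.23, SE 0.55, limma adjusted p = 0.0139), with 1.84 CPM in knockout replicate 1 and 22.4 CPM in replicate 2. For Hspa1b, Hspa1a and Slc15a2 the SE is moderated towards the variance trend, and is smaller than their own spread between libraries would give. Gm5801, a processed pseudogene, was at 19.9 and 22.0 CPM in wild type and was listed at 0 in both knockout libraries (limma adjusted p = 0.00114).

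These 4 were the genes past an adjusted p of 0.05 among the 10486 tested, and all 4 were lower in knockout. In GRCm38 with the GENCODE M21 annotation, Hspa1b (34956436 to 34959238) and Hspa1a (34969190 to 34972156) are neighbours on chromosome 17. The protein-coding gene Slc15a2 lies on chromosome 16 (36750177 to 36784962) and Gm5801 on chromosome 14 (56010536 to 56011315). Gm5801 fell outside the naming rule and was chosen after its values were seen. Hspa1a and Hspa1b are close copies of each other, and Gm5801 is 99.2% identical to the transcript of Ube2j2, so the authors' counting could split reads between them and their separate values are uncertain. Their estimated reads in wild type were fractional, at 565.3 and 1669.9 for Hspa1b, 213.6 and 773.1 for Hspa1a and 36.3 and 52.4 for Gm5801. Those of Foxp3 were fractional too (293.3 and 334.1), and those of Slc15a2 whole. Reads were thus counted in parts, but with which genes they were shared is not shown. Ube2j2 was at 27.7 and 36.0 CPM in wild type and at 34.0 and 30.4 CPM in knockout. The authors' deposited table put 3 genes under an adjusted p of 0.05, Hspa1b, Hspa1a and Slc15a2, all lower in knockout, and gave Gm5801 an adjusted p of 1.

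Slc15a2 did not pass with median-of-ratios size factors (adjusted p = 0.118, range over alternatives 4.27e-10 to 0.947) or a pseudocount of 0.1 (0.0647). Gm5801 did not pass with that pseudocount (0.0798, range 0.000288 to 0.435), and with no low-value filter 0 genes passed by limma (1305 at an unadjusted p under 0.05). All 4 genes passed without each library in turn, but the sizes moved. Log2 fold changes were -1.86 for Hspa1b and -2.29 for Hspa1a without wild-type replicate 2, against -3.04 and -3.76 without wild-type replicate 1, and for Slc15a2 -1.70 without knockout replicate 1 and -4.75 without knockout replicate 2. The genes past the threshold then numbered 16 without wild-type replicate 2, 11 of them higher in knockout, and 14 without knockout replicate 2, all lower.

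Around Slc15a2, 16 of the 18 other tested genes within 1 Mb were lower in knockout, with a median log2 fold change of -0.27. That median ran from -0.17 without wild-type replicate 1 to -0.34 without knockout replicate 1. None of the 18 passed over all genes tested, and 1 had an unadjusted p under 0.05. Of these neighbours, chosen after their values were seen, the neuronal gene Stxbp5l was lowest, at 6.02 and 7.99 CPM in wild type and 0.31 and 3.81 CPM in knockout (log2 fold change -1.66), and the DNA polymerase gene Polq highest (0.44). Stxbp5l rested on few reads, and was at -0.72 without knockout replicate 1 and -2.60 without knockout replicate 2. Some gene families that T cells do not use, given below, also summed lowest in knockout replicate 1. The costimulatory ligand gene Cd86 had a log2 fold change of -0.32.

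**Figure D1:**
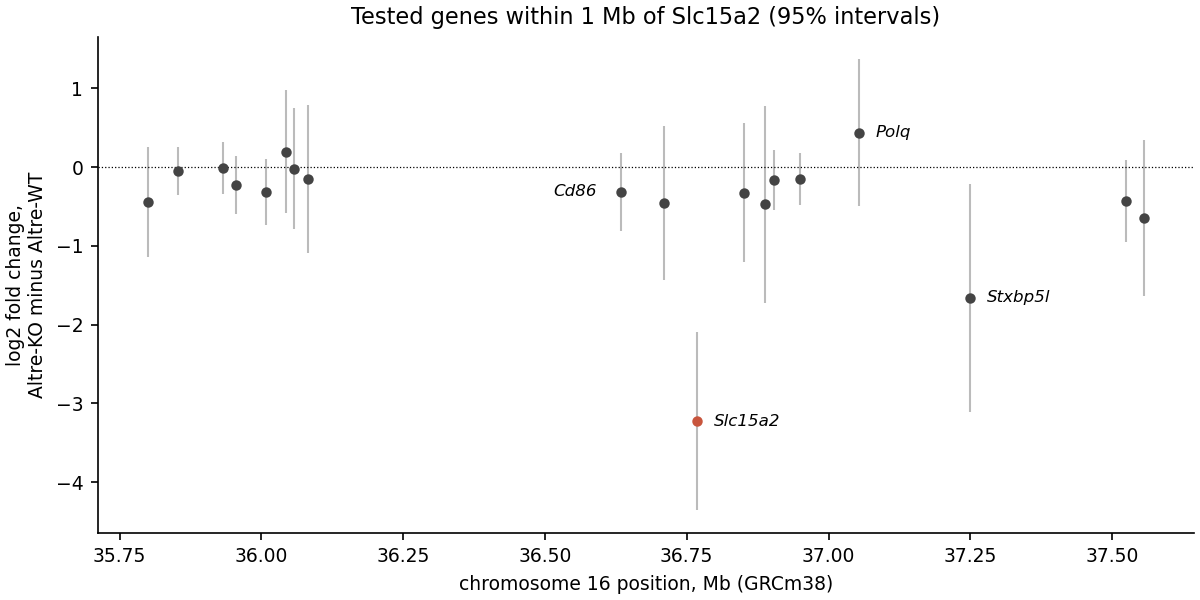
Log2 fold change, knockout minus wild type on the log2(CPM + 1) scale (vertical axis), with 95% intervals from limma (bars), of Slc15a2 (red) and the 18 other tested genes within 1 Mb (dark grey) against position on chromosome 16 in GRCm38 (horizontal axis, Mb), n = 2 libraries per genotype. Slc15a2 lies at -3.23, below its neighbours, which lie between -1.66 and 0.44.

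**Figure D2:**
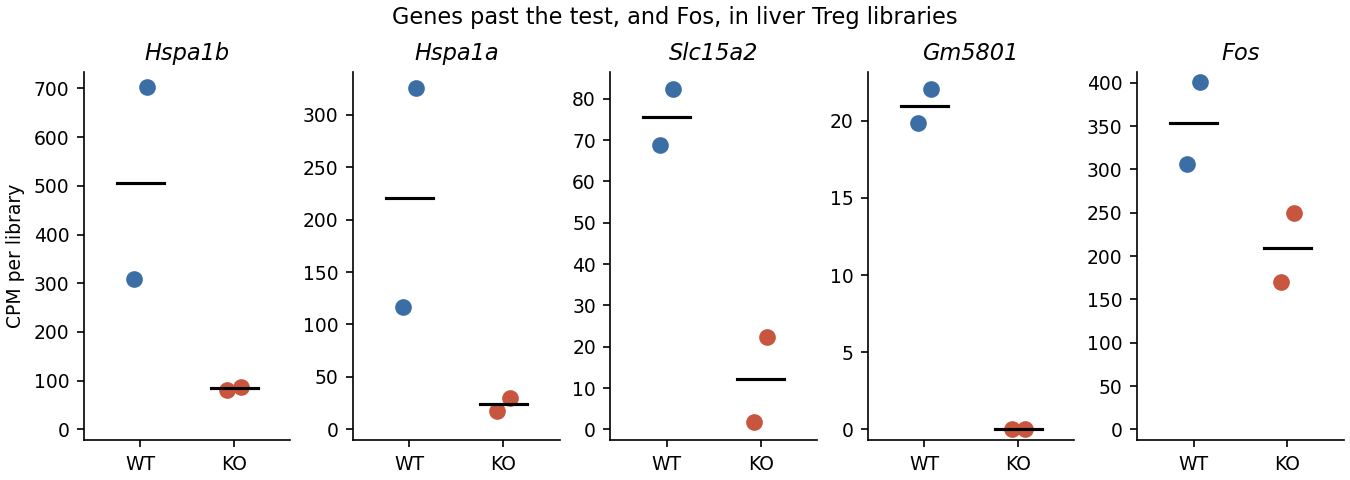
CPM per library (vertical axes, linear, separate scale for each gene) for the 4 genes past the test and for Fos, with wild-type libraries (WT) in blue, knockout libraries (KO) in red and a black line at each genotype's mean, n = 2. Each gene's knockout points lie below its wild-type points, from 87.4 CPM or less against 309.1 CPM or more for Hspa1b to 0 against 19.9 CPM or more for Gm5801.

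No transcript passed the test as higher in knockout. Among genes above both wild-type values in both knockout libraries, the 5 with the smallest p are given as values. Tnfrsf25, a receptor of the TNF-receptor family found on Tregs, was at 60.2 and 69.4 CPM in wild type and at 104 and 103 CPM in knockout, and Lman1, a cargo receptor between endoplasmic reticulum and Golgi, at 44.3 and 45.0 CPM against 74.7 and 73.7 CPM. Ranbp6, of the importin family, had a log2 fold change of 0.66, the linker histone gene Hist1h1b 0.95 and the histone gene Hist1h4m 2.68, from 0.34 and 0.15 CPM to 9.96 and 4.74 CPM; replication-dependent histone genes occur in similar copies, so the values of single members are uncertain. The limma adjusted p of all 5 was 0.999. At an unadjusted p under 0.05, 151 genes were higher and 233 lower, 384 in all where 524.3 are expected by chance, and limma-voom on estimated reads likewise called 0 genes higher and 4 lower. The 2 genotypes did not overlap for 3232 genes, 30.8% of those tested, and chance alone gives 33.3%.

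The dissociation stress list, immediate early and heat-shock genes that tissue handling raises, stood lower in knockout (camera adjusted p = 4.77e-05), although its members went both ways. With an estimated correlation, on few degrees of freedom, the list had a camera p of 0.0499 unadjusted and 0.981 adjusted. That adjusted p was the highest over 13 alternatives (lowest 1.91e-21). Of 23 members 13 were lower and 10 higher, with a median log2 fold change of -0.03 and a mean of -0.35. Beside Hspa1a and Hspa1b, the AP-1 transcription factor gene Fos was at 306 and 401 CPM in wild type and at 170.2 and 249 CPM in knockout (log2 fold change -0.76, SE 0.18, limma adjusted p = 0.683, with 0.0415 without knockout replicate 2 and 0.116 to 0.997 without each of the others). Its relative Fosb had a log2 fold change of -0.67. Both passed adjusted over the list alone, where 4 members did, all lower, against 2 over all genes tested. The other 8 chaperone genes in the list, named after their values were seen, did not pass. Their log2 fold changes were -0.38 for Hsp90aa1, -0.31 for Dnajb1, -0.27 for Hsp90ab1, -0.03 for Hsph1, 0.02 for Hspe1, 0.04 for Hspd1, 0.07 for Dnaja1 and 0.25 for Hspa8. Without Hspa1a and Hspa1b, an alternative chosen after the data were seen, it had an adjusted p of 0.0943.

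Treg identity genes also stood lower as a list in knockout, with 20 of 26 members lower, a median log2 fold change of -0.12 and a camera adjusted p of 0.00943. With an estimated correlation (-0.039), on few degrees of freedom, the camera p was 0.0613 unadjusted and 0.981 adjusted. That adjusted p was the highest over 13 alternatives (lowest 1.11e-05). As this correlation lay below the preset 0.01, correlation between members does not account for the higher p. No member passed over all genes or adjusted over the list alone. The members with the smallest p were the costimulatory receptor gene Icos, at 156 and 166 CPM in wild type and at 120.3 and 124 CPM in knockout, the orphan receptor gene Gpr83, at 159 and 151 CPM against 123 and 119.8 CPM, and the inhibitory receptor gene Tigit, at 32.8 and 31.1 CPM against 19.0 and 23.3 CPM. The list did not pass without wild-type replicate 1 (adjusted p = 0.0945) or without wild-type replicate 2 (0.101).

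No gene of the Treg panel passed the test between genotypes, and all 13 tested had a limma adjusted p of 0.999. Foxp3 had a log2 fold change of -0.40 (95% interval -0.87 to 0.08), which rested on knockout replicate 1 and was 0.11 without that library. The Helios gene Ikzf2 was at 1236 and 1253 CPM in wild type and at 1226 and 1272 CPM in knockout, and Il2ra, Ctla4 and Yy1 had log2 fold changes of -0.09, -0.12 and 0.01. Intervals were wide for the cytokine genes Il10 (-1.97 to 0.40), Ifng (-1.89 to 0.33) and Areg (-0.95 to 1.41), whose levels lay at 18.1 CPM or less. Il1rl1, the receptor for interleukin-33 on tissue Tregs, had a log2 fold change of -0.49, Klrg1 -0.56, Tbx21 -0.46, Gata3 0.39 and Tcf7 -0.32. Il1rl1 was at -0.18 without wild-type replicate 1, Tbx21 at -0.14 without wild-type replicate 2 and Klrg1 at -0.26 without knockout replicate 2. The sign changed for Gata3 without knockout replicate 2 (-0.035) and for Tcf7 without knockout replicate 1 (0.028). It also changed without a single library for Il2ra, Ctla4, Ikzf2, Yy1, Il10, Ifng and Areg. The cell cycle inhibitor gene Cdkn1a was below the filter, at 2.19 and 0 CPM in wild type and 0 and 2.54 CPM in knockout.

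**Figure D3:**
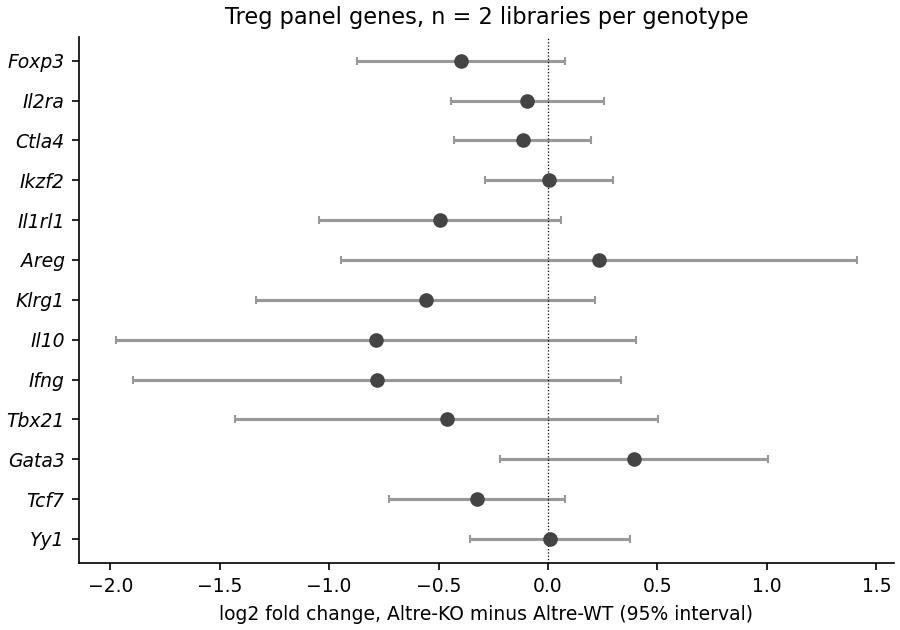
Log2 fold change, knockout minus wild type on the log2(CPM + 1) scale (horizontal axis), with its 95% interval from limma (bars), for the 13 tested panel genes, n = 2 libraries per genotype. All 13 intervals include 0, from Ikzf2 at 0.00 to Il10 at -0.79.

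Type I interferon-stimulated genes were lower in knockout as a list: 24 of 32 members were lower, with a median log2 fold change of -0.12 and a camera adjusted p of 0.0336. With an estimated correlation (0.048), on few degrees of freedom, the camera p was 0.170 unadjusted and 0.981 adjusted. That adjusted p was the highest over 13 alternatives (lowest 0.0170). The smallest p values belonged to Rtp4 (30.1 and 36.1 CPM in wild type, 23.0 and 11.9 CPM in knockout), to Irf7, a transcription factor of the interferon response (66.7 and 75.7 against 51.1 and 45.3 CPM), and to Oas3, an antiviral synthetase gene (41.0 and 33.6 against 23.0 and 28.4 CPM). None of the members passed over all genes tested or adjusted over the list alone. The list did not pass without wild-type replicate 1 (adjusted p = 0.0621), wild-type replicate 2 (0.279) or knockout replicate 2 (0.221).

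Nuclear-encoded subunits of respiratory complex I were higher in knockout as a list, with 24 of 33 members higher, a median log2 fold change of 0.14 and a camera adjusted p of 0.0336. With an estimated correlation of 0.428, far above the preset 0.01, the camera p was 0.480 unadjusted and 0.981 adjusted. That adjusted p was the highest over 13 alternatives (lowest 0.000264), and fry gave an unadjusted p of 0.583. The call thus rests on the low preset correlation. Ndufb5 was at 46.5 and 46.2 CPM in wild type and at 62.1 and 63.1 CPM in knockout, Ndufs4 at 40.5 and 39.1 CPM against 59.4 and 47.0 CPM, and Ndufa3 at 20.8 and 36.6 CPM against 43.2 and 34.3 CPM. No member passed over all genes or adjusted over the list alone. The direction of the list turned without knockout replicate 1 (adjusted p = 0.956), and the call ended without wild-type replicate 1 (0.101) or wild-type replicate 2 (0.214). Knockout replicate 1 also had the largest share of its library's reads on listed genes, 32.8%, against 18.8% to 21.5% in the other libraries. Complexes II to V had 24 of 40 members higher, with a median log2 fold change of 0.03, a mean of -0.02 and a camera direction of higher (adjusted p = 0.839), and mitochondrial ribosomal proteins 39 of 76 (adjusted p = 0.409). Their members with the smallest p were the ATP synthase genes Atp5g1 (log2 fold change -0.84) and Atp5l (-1.55, and -0.35 without knockout replicate 2, where it was listed at 0), the cytochrome oxidase gene Cox7a2 (0.40), and Mrps7 (0.63), Mrpl28 (0.63) and Mrpl22 (1.25). Mrpl28 was at 0.34 without knockout replicate 1 and Mrpl22 at 0.70 without wild-type replicate 1. Without knockout replicate 2 these lists passed as higher, with adjusted p of 0.0141 and 0.00927, and without knockout replicate 1 their direction turned (0.168 and 0.409).

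Cholesterol and fatty acid synthesis genes had 17 of 28 members higher in knockout, with a median log2 fold change of 0.13 and a camera adjusted p of 0.101. Its members with the smallest p were the fatty acid elongase gene Elovl6 (log2 fold change 0.72, and 0.45 without wild-type replicate 1), the sterol desaturase gene Sc5d (0.48) and Hmgcs1 (0.47), which encodes an early enzyme of the mevalonate pathway. Tissue and effector Treg genes had 16 of 26 members lower (adjusted p = 0.165), among them the chemokine receptor gene Ccr8, at 36.8 ± 2.10 CPM in wild type and 20.2 ± 3.10 CPM in knockout (SD, n = 2, log2 fold change -0.84, SE 0.29, limma adjusted p = 0.999), and the integrin gene Itgae (log2 fold change -0.30). The adjusted p of the tissue and effector list depended on the library left out, at 0.00759 without wild-type replicate 1, 0.942 without wild-type replicate 2, 0.368 without knockout replicate 1 and 0.148 without knockout replicate 2. With genes of a mean of at least 20 CPM, an alternative chosen after the data were seen, the synthesis list passed as higher and the tissue and effector list as lower (adjusted p = 0.0269 for both). TGF-beta signalling genes had 11 of 16 members lower (adjusted p = 0.223), with log2 fold changes of -0.40 for Ski and -0.21 for Tgfbr2. These rested on knockout replicate 1, and were -0.13 and -0.018 without it.

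Suppressive molecules had 11 of 16 members lower (adjusted p = 0.404), while the granzyme gene Gzma was at 1.09 and 1.26 CPM in wild type and at 6.12 and 7.20 CPM in knockout (limma adjusted p = 0.999) and Lrrc32 had a log2 fold change of -0.32, or -0.16 without knockout replicate 1. With genes of a mean of at least 20 CPM this list passed as lower (adjusted p = 0.0329). Cell cycle genes went both ways. G2 and mitosis genes had 16 of 24 members higher (adjusted p = 0.366), with log2 fold changes of 0.69 for Kif11 and 0.90 for Cdk1 and of -0.38 for Mki67. Kif11 had a log2 fold change of 0.091 without wild-type replicate 2, and Mki67 -0.037 without knockout replicate 1. S phase genes had 19 of 26 members lower (adjusted p = 0.966), with log2 fold changes of 1.08 for Rrm2, -0.39 for Mcm4 and 0.37 for Rrm1. Chemokine receptors and homing genes had 17 of 29 members lower (adjusted p = 0.446), with log2 fold changes of -0.42 for the integrin gene Itgal and 0.84 for Gpr55. The value of Itgal rested on knockout replicate 1, with a log2 fold change of -0.0019 without that library and of -0.84 without knockout replicate 2 (limma adjusted p = 0.0415). Resting and naive T cell genes divided evenly, 9 lower and 9 higher (adjusted p = 0.843), with 0.43 for Id3, -0.45 for Lef1 and -0.31 for Il7r. Helper T cell cytokine genes divided likewise, 7 and 7 (adjusted p = 0.966), with -0.26 for Cxcr3 and 0.70 for Ccl5, which was -0.37 without wild-type replicate 2. None of the members of these lists passed over all genes tested or adjusted over the list alone. The other 18 lists tested had adjusted p between 0.446 and 0.980. They covered T cell receptor, NF-kB, interleukin-2 and interferon-gamma responses, glycolysis, the citric acid cycle, fatty acid oxidation, antioxidant, p53, unfolded protein and cell death genes, YY1 and Polycomb genes, mitochondrial dynamics, cytosolic ribosomal proteins and 4 other cell types. By fry, 0 of the 33 lists passed (2 at an unadjusted p under 0.05), and with an estimated correlation 0 passed (1 at an unadjusted p under 0.05). The test with an estimated correlation had too few degrees of freedom to decide on the calls.

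**Figure D4:**
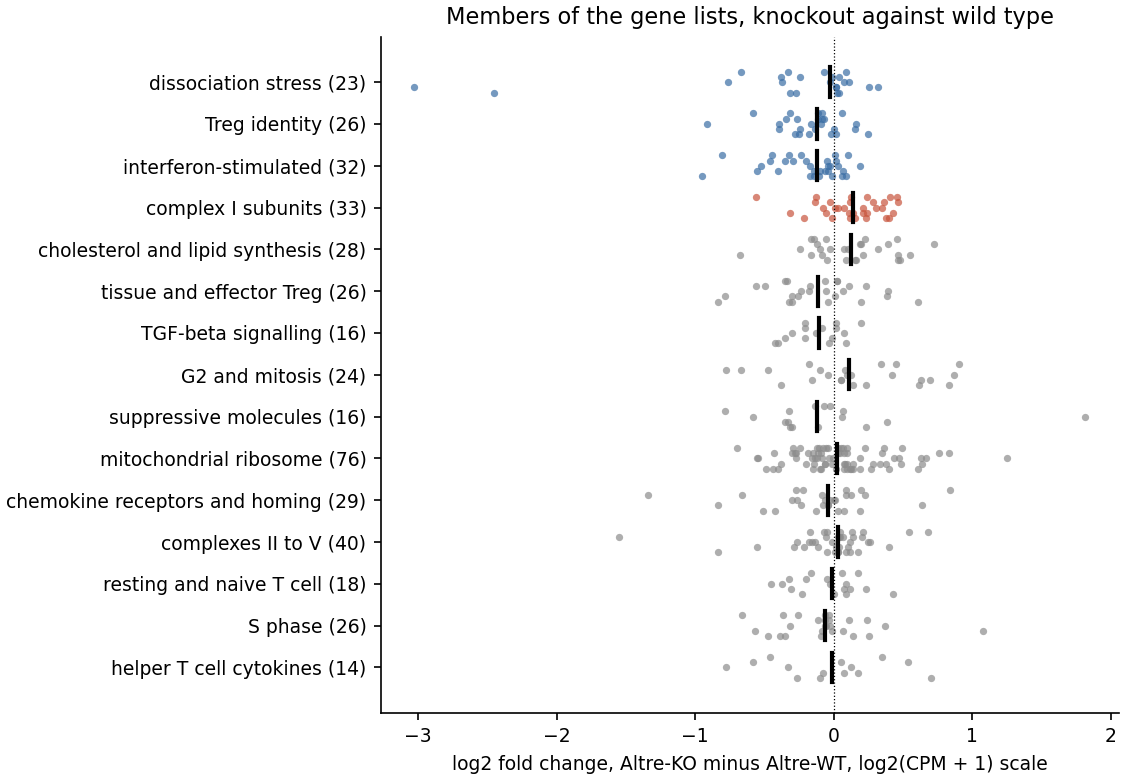
Log2 fold change, knockout minus wild type on the log2(CPM + 1) scale (horizontal axis), of each tested member (points, spread vertically for visibility) of 15 gene lists, with the number of tested members in brackets and a black bar at the list's median. Lists past a camera adjusted p of 0.05 are blue where lower and red where higher in knockout; their medians lie between -0.12 and 0.14, and the 2 points farthest to the left are Hspa1a at -3.03 and Hspa1b at -2.45.

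Marker transcripts of other liver and blood cells were present at levels that mostly overlapped between genotypes. Summed hepatocyte markers came to 57.6 ± 14.2 CPM in wild type and 64.8 ± 14.5 CPM in knockout (SD, n = 2), with Alb listed at 0 in all 4 libraries. Kupffer cell, macrophage and monocyte markers summed to 865 ± 130 CPM and 872 ± 177 CPM, led by Ctss at 412 to 469 CPM, and B and plasma cell markers to 257 ± 115 CPM and 221 ± 21.1 CPM, led by Jchain. Sums of 2 of the 11 marker lists did not overlap between genotypes: gamma-delta T, NKT, ILC2, mast cell and basophil markers were at 55.8 and 51.7 CPM in wild type and 41.3 and 44.9 CPM in knockout, and cholangiocyte markers at 26.7 ± 3.26 CPM and 22.3 ± 2.56 CPM. An exact permutation test of 2 libraries against 2 cannot give a p below 0.333, and no other test was made of these sums.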

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

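No test was chosen for this result. The share of each library's implied reads that lay on listed genes was a measure outside the comparison of genes, and both knockout libraries exceeded both wild-type libraries in it. It was 32.8% in knockout replicate 1 and 21.5% in knockout replicate 2, above the higher wild-type value of 20.6%. Knockout replicate 1 lay farther from the other 3 libraries, at 18.8% to 21.5%, than these lay from each other. No explanation was tested.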

How the results depend on the processing

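Alternatives chosen only after the data were seen were library totals without 3 abundant RNAs, a mean of at least 20 CPM, the stress list without Hspa1a and Hspa1b, and the ranking by the authors' p-value. The planned tests that need counts, DESeq2 and the ranking by its statistic, were not run, as the values are CPM. Hspa1b and Hspa1a passed in 15 of 16 alternatives each, Slc15a2 in 13 of 16 and Gm5801 in 12 of 14, all with lower values in knockout; adjusted p ran from 8.61e-31 to 0.718 for Hspa1b, 1.22e-31 to 0.811 for Hspa1a, 4.27e-10 to 0.947 for Slc15a2 and, over 14, from 0.000288 to 0.435 for Gm5801. The highest came with no low-value filter, which brings in genes listed at 0 everywhere and left 0 genes changed and 0 lower (1305 at an unadjusted p under 0.05). A pseudocount of 0.1 left 2 genes, both lower. Median-of-ratios size factors left 3, all shared with the reported 4. Of 930 values of single named genes, 908 kept direction and side of the threshold, 7 lost and 3 gained a call, and 12 changed sign.

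Without each library in turn, where the lone library of a genotype is assumed to vary like the others, the genes changed numbered 6 to 16, with 0 to 11 higher and 4 to 14 lower, and all 4 called genes passed each time. Log2 fold changes then spanned 0 for Foxp3 (-0.91 to 0.11), Il2ra (-0.28 to 0.091), Ctla4 (-0.24 to 0.0050), Ikzf2 (-0.022 to 0.031), Areg (-0.19 to 0.66), Il10 (-1.63 to 0.058), Ifng (-1.56 to 0.0029), Gata3 (-0.035 to 0.82), Tcf7 (-0.68 to 0.028), Yy1 (-0.080 to 0.099) and Ccl5 (-0.37 to 1.77). Of 56 named genes not past the threshold, 33 moved over 1.5 times or changed sign, and 11 of these changed sign. The other 22 were Itgal (-0.84 to -0.0019), Kif11 (0.091 to 1.30), Mki67 (-0.73 to -0.037), Rrm1 (0.018 to 0.72), Tgfbr2 (-0.40 to -0.018), Ndufa3 (0.072 to 0.86), Atp5l (-2.76 to -0.35), Ski (-0.68 to -0.13), Il1rl1 (-0.81 to -0.18), Klrg1 (-0.86 to -0.26), Tbx21 (-0.79 to -0.14), Elovl6 (0.45 to 1.00), Mrpl28 (0.34 to 0.92), Mrpl22 (0.70 to 1.79), Lrrc32 (-0.48 to -0.16), Rtp4 (-1.40 to -0.50), Ndufs4 (0.24 to 0.57), Itgae (-0.41 to -0.19), Id3 (0.27 to 0.59), Il7r (-0.44 to -0.18), Mcm4 (-0.55 to -0.24) and Fos (-1.04 to -0.49). The lists past the threshold numbered 1 (without wild-type replicate 2) to 6 (without knockout replicate 2). Adjusted p ranged from 0.0147 to 0.101 for Treg identity, 0.0174 to 0.279 for interferon-stimulated genes and 0.000264 to 0.956 for complex I, whose direction turned without knockout replicate 1. Directions of lists that did not pass also turned, with adjusted p from 0.313 to 0.95 for resting and naive T cell genes, 0.516 to 0.958 for helper T cell cytokines, 0.0141 to 0.942 for complexes II to V, 0.00927 to 0.942 for mitochondrial ribosomal proteins and 0.259 to 0.942 for S phase. Apart from the smaller number of libraries, the cause was not tested.

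With an estimated correlation 0 lists passed (camera adjusted p = 0.981 for each of the 4 called), in a test with too few degrees of freedom to decide. By fry 0 passed, with adjusted p of 0.0606 for Treg identity, 0.695 for dissociation stress and interferon-stimulated genes and 0.947 for complex I. With a mean of at least 20 CPM 7 lists passed, the 3 gained among those described being cholesterol and fatty acid synthesis (higher) and tissue and effector Treg genes (lower), both at 0.0269, and suppressive molecules (lower, 0.0329). Without Hspa1a and Hspa1b the stress list had an adjusted p of 0.0943, by the loss of its strongest members. Ranking by the authors' p-value turned S phase (0.948) and gained tissue and effector Treg (0.0331) and TGF-beta signalling genes (0.0399), both lower. The difference in mean correlation within and across genotypes was 0.00062, and 0.00245 with a prior of 0.5.

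Whether the replicate numbers pair the libraries is not given by the labels. The correlation across genes of replicate 1 minus 2 between genotypes was -0.010, over 2 pairs, which are too few to tell. With the replicate block 6 genes changed, 1 higher (Lars2) and 5 lower, the 4 called and Fos (limma adjusted p = 0.0346). The call of Lars2 rested on knockout replicate 2, at 2542 CPM. Knockout replicate 1, at 189 CPM, lay below both wild-type libraries, at 206 and 283 CPM. With that block 4 lists passed, among them dissociation stress (camera adjusted p = 3.07e-07). At 1828770 to 3266130 estimated reads per library, a single read is 0.306 to 0.547 CPM, so genes of a few CPM rest on few reads.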

Other observations

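Tests chosen only after the result was seen were those of the summed copies, of the rise that Ube2j2 would need, of library totals without abundant RNAs, of the rest of the stress list, of the size of the region's shift, and of olfactory receptor reads against reads outside listed genes. Ribosomal RNA and Lars2, which encodes a mitochondrial leucyl-tRNA synthetase, set knockout replicate 2 apart. Rn45s, the precursor of ribosomal RNA, was at 37757 CPM there and between 13699 and 16726 CPM in the other 3 libraries, and Lars2 was at 2542 CPM there and between 189 and 283 CPM in the others. Neither passed the test between genotypes as reported (limma adjusted p = 0.999 for both). Lars2 passed as higher in 4 alternatives, 3 of them the fits without wild-type replicate 1, wild-type replicate 2 or knockout replicate 1, and Rn45s in the fit without knockout replicate 1. With library totals that leave out Rn45s, Rpph1 and Rmrp, the same 4 genes passed.

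The lower Hspa1a and Hspa1b in knockout did not come from reads moving between the 2 copies. Their sum fell from 426 and 1027 CPM to 98.9 and 117 CPM (log2 fold change -2.61, 95% interval -3.11 to -2.10). The direction did not rest on a single library, as both genes were lower in both knockout libraries than in both wild-type libraries. The highest adjusted p of either gene over the 4 fits without a library was 0.0325 by limma. Each such fit takes the lone library to vary like the others, so it cannot show how far the calls rest on it. Stress during handling of the wild-type cells stays open. The other 21 members of the stress list, 11 of them lower and 10 higher, had a camera p of 0.0114 as lower. With an estimated correlation the camera p was 0.109, on too few degrees of freedom to decide. An effect of Altre on these genes also stays open and was not tested apart from handling, because the labels give no day or batch. The splits of the 4 libraries into 2 and 2 are 3, too few for a share under 0.05; the genotypes gave 4 genes and the highest other split also 4, so that 2 of the 3 splits gave as many.

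Slc15a2 lay at 1.84 and 22.4 CPM in knockout, below both wild-type libraries, so its direction did not rest on a single knockout library. The log2 fold change did depend on the library, at -1.70 without knockout replicate 1 and -4.75 without knockout replicate 2. Both fits drop the spread between the knockout libraries. Their highest adjusted p, 0.0392 by limma, therefore cannot show how far the call rests on either library. A shift of the region may add to the fall of Slc15a2. The 18 neighbours had a median log2 fold change of -0.27, a level reached by 0.112% of 9796 windows of as many neighbouring genes. That median was -0.17 without wild-type replicate 1. The upper end of the interval for Slc15a2, -2.10, lay below the lowest neighbour, Stxbp5l at -1.66 (interval -3.11 to -0.21). In the fit without knockout replicate 1, Slc15a2 was at -1.70, the lowest neighbour was Rabl3 at -0.88, and Stxbp5l was at -0.72. Slc15a2 was picked for its low value and its interval overlaps that of Stxbp5l. These values therefore do not decide whether the shift is all of the difference. For Gm5801, reads can be shared with Ube2j2, whose transcript is 99.2% identical over its whole length, yet had all of its reads moved there, Ube2j2 would be higher in knockout by 0.72 on the log2 scale, above its interval of -0.55 to 0.60. The sum of both had a log2 fold change of -0.69 (95% interval -1.21 to -0.17, limma adjusted p = 0.999), a value favoured by the choice of Gm5801 for its 0 in knockout; a move of part of the reads stays open. A strain difference around these genes and an effect of Altre stay open and were not tested.

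Some families of genes that T cells do not use summed lower in knockout. Olfactory receptor genes, 1125 in number, summed to 373 and 339 CPM in wild type and to 109.6 and 229 CPM in knockout, and vomeronasal receptor genes to 133 and 118 CPM against 48.9 and 104 CPM. Fewer background reads in the knockout libraries are a candidate explanation that stays undecided: of 4 further silent families, 2 (vomeronasal receptor and keratin-associated genes) summed lower in both knockout libraries, while taste receptor genes were at 13.7 and 11.3 CPM against 13.5 and 12.3 CPM and defensin genes had 4 reads or fewer. Olfactory receptor reads did not keep step with the reads outside listed genes. Their share relative to such reads was lower in both knockout libraries, with a mean 0.667 times that of wild type. What the reads outside listed genes hold is not known, so this does not decide on background in general. An effect of genotype on silent genes was not tested.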
